A study of Homo sapiens with 9 samples.

How the data were processed

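The data are droplet single-cell RNA sequencing libraries of MDA-MB-231 cells in 3 groups of 3 samples, with groups and replicate numbers taken from the labels. The authors deposited 1 table of the whole series with 21849 gene rows, 2547 barcodes in columns and 5 rows of attributes per barcode, and each barcode was assigned to its sample by name. Per the submitters' processing notes the reads were aligned with STAR 2.6.1 to hg38. The tool that counted reads, the annotation, the use of strand and the collapsing of molecular identifiers are not given in the sources used here.

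The table's name calls the values normalized, but the deposited values are in the unit of expected counts. Of the nonzero values 96.6% are whole numbers within 0.001, library sums differ, and the deposited mitochondrial percent of each barcode equals the sum of its mitochondrial genes over the deposited total count (ratio 1.00). The expected counts were rounded after summing. The table sums to 56.7% of the total count attribute (1.35% to 86.1% per barcode), so counts outside the listed genes cannot be seen here. Every listed gene has a total of at least 30 counts. A set of 20 rows whose names had become dates was left out, with 0.175% of the counts, which leaves 21829 genes. The table holds 2536 distinct barcode sequences among 2547 columns. If molecular identifiers were not collapsed, counts include PCR copies, so intervals and floors cover counting error only.

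Counts were summed over the barcodes of each library, since barcodes are not replicates. The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, glmQLFit and glmQLFTest over all 9 libraries with a mean per group and no block, which tested 15979 genes. The planned test for normalized values, limma on log2 values plus 5, became an alternative because the unit turned out to be counts. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 per comparison. The common dispersion was 1.34, a biological coefficient of variation of 1.16. Gene lists with at least 5 measured members were tested with camera of limma 3.58.1 with the correlation preset at 0.01, two-sided, adjusted over the 28 lists of a comparison, and again with an estimated correlation and with fry. CPM values use TMM library sizes, and shares of a library's counts use plain sums. A fold against a group at 0 was bounded with a floor of 3 counts over the group.

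The named genes follow a rule. In naive against none, primed against none and primed against naive, it takes the 12 genes of smallest p per direction among those that pass, or, where fewer pass, up to 6 per direction by unadjusted p, said not to have passed. It adds up to 4 members of smallest p from each list described, and CTNNB1, MYC, CCND1, CDKN1A, CDKN1B, MKI67, CD44, VIM, POU5F1, SOX2 and NANOG where measured. This rule, the lists, the tests and most alternatives were fixed before the data were examined. The lists are S phase, G2/M phase, CDK inhibitors and quiescence, pluripotency and cancer stem cell, Wnt and beta-catenin, epithelial, mesenchymal and matrix, TGF-beta and BMP, Notch, ribosomal proteins, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, heat shock, immediate early, interferon response, NF-kB and cytokines, cholesterol synthesis, p53 targets, DNA repair, histones, ferritin and redox, proteasome, vesicle biogenesis, apoptosis, MSC markers, blood cell markers and RNA quality. Locations come from GENCODE release 29 on GRCh38 and were found for 66 of 73 named genes. Of these, 39 overlap another gene, and without a stated use of strand their counts may include its reads.

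Measures per barcode were compared between groups with exact two-sided permutation tests of the library values in Python 3.11.15 with scipy 1.17.1, where 3 libraries against 3 allow no p under 0.1 and 6 against 3 none under 0.0119. A gene was detected in a barcode at a count above 0.5. The G2/M score was the mean log value of 52 genes minus that of 100 genes of matched mean, with the limit at the mean plus 1 SD. Clusters used scanpy 1.11.5 with 2000 variable genes, 20 components and a resolution of 0.5. No doublet caller was run, no barcodes were removed, and free RNA was not corrected.

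Naive and primed samples of the same number share a labelled exosome source, so their numbers pair them. As a check, deviations from the group means correlated across genes within naive and primed pairs at r = 0.161, 0.0702 and 0.155. The alternatives were the replicate number as a block, DESeq2 1.42.0, limma with pseudocounts of 1 and 20, median-ratio scaling, other filters, the fit to the compared samples alone, and each library left out in turn. Added after the data were seen were a robust dispersion, limma with a pseudocount of 5, the deposited total count as library size, barcodes with over 2% of their library's counts left out, barcodes sharing 11 of 12 bases left out, barcodes with the gene in place of counts, the 4 libraries of fewest detected genes left out, and thinning.

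The fit and the list test were tested on simulated data for naive against none. With a dispersion of 0.05, 100% of 100 genes changed by 2 on the log2 scale and 100% of 100 changed by 4 were recovered among 15768 genes, with 11 false calls. With the dispersions of these data, 0% at log2 2 and 2% at log2 4 were recovered among 15434 genes, with 0 false calls. A list of 50 genes raised 2-fold had a camera p of 3.59e-96 at the low dispersion and 0.0149 at the dispersions of these data, and an unchanged list 0.846 and 0.879. The simulated genes were drawn independently of each other. The list values therefore do not show how often camera calls unchanged lists whose members correlate, as those of these data do.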

Results

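The series measured the RNA of single MDA-MB-231 cells, a human breast cancer line, that had been transfected with an Oct4A-GFP construct and kept for 7 days in 2% exosome-depleted serum. Exosomes are small vesicles that cells release, and those given here came from mesenchymal stem cells (MSCs), a stromal cell type. In 3 control libraries the cancer cells received no exosomes, in 3 libraries they received exosomes of naive MSCs, and in 3 they received exosomes of primed MSCs, which had shared a transwell with MDA-MB-231 cells for 24 hours. Each dose was 100000000 exosomes and was given every 48 hours. The design asks how the cancer cells differ with naive or primed MSC exosomes from cells without exosomes, and from each other.

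The 9 libraries held 2547 cell barcodes. The control libraries had 160, 507 and 158 barcodes with 5703353, 5790406 and 14303820 counts. The naive libraries had 159, 351 and 211 barcodes with 5380462, 7476731 and 19027623 counts, and the primed libraries had 649, 184 and 168 barcodes with 4030265, 2028317 and 10950767 counts. The median number of genes detected per barcode ran from 824 in primed replicate 1 to 5042 in naive replicate 3, and was 1406 in control replicate 2, 967 in naive replicate 2 and 1246 in primed replicate 2. A single barcode held between 2.63% (primed replicate 3) and 39.3% (naive replicate 2) of its library's counts. Single genes could also rest on 1 barcode. Among genes with at least 30 counts in a library, 1 barcode held most of the gene's counts in 6.47% (control replicate 1) to 48.4% (primed replicate 2). Libraries of a group resembled each other little more than libraries of different groups, with a median correlation of log2 CPM across genes of 0.608 within groups (range 0.443 to 0.793) and 0.578 between groups (0.442 to 0.801). The labels give the libraries of each exosome group different exosome sources, but do not say whether the control libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

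**Figure D1:**
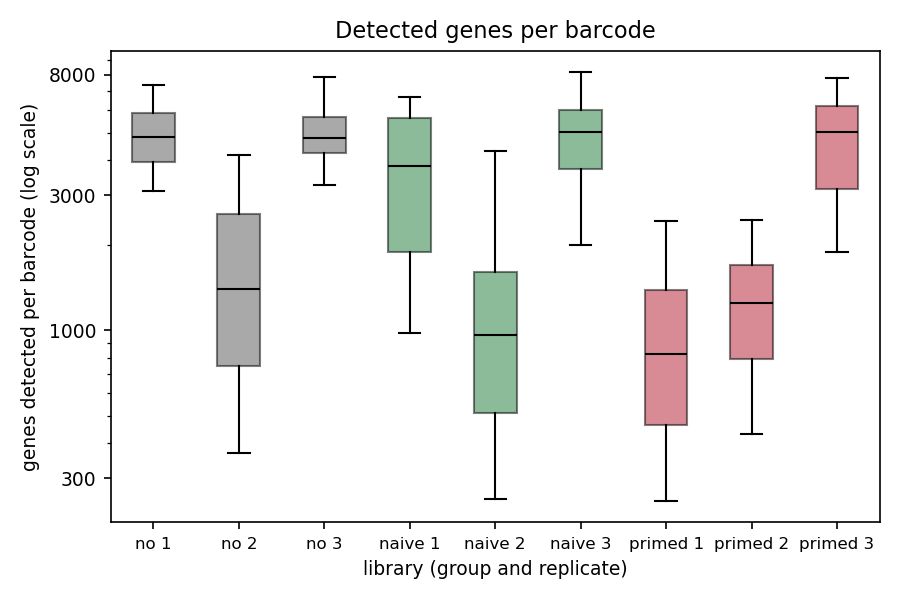
Genes detected per barcode on a log axis for the 9 libraries by group and replicate, with boxes from the lower to the upper quartile, the median as a line and whiskers from the 5th to the 95th percentile. Medians run from 824 genes in primed replicate 1 to 5042 in naive replicate 3, and the lowest library is at 1406 among the controls, 967 among the naive and 824 among the primed libraries.

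With naive exosomes, ribosomal protein genes and the nuclear genes of oxidative phosphorylation fell as lists against no exosomes. The camera test of limma with a preset inter-gene correlation gave an adjusted p of 2.90e-06 for ribosomal proteins and 0.00188 for oxidative phosphorylation, and adjusted p = 0.798 for both with an estimated correlation. Of 78 ribosomal protein genes, which encode the protein part of the cytosolic ribosome, 71 had a lower estimate with naive exosomes, and the median log2 fold change was -0.46. RPL35 averaged 1176 ± 190.0 CPM with naive exosomes and 2491 ± 274 CPM without (SD, n = 3 each; log2 fold change -1.08, SE 0.50), and RPS21 averaged 994 ± 404 and 2203 ± 438 CPM (log2 fold change -1.15, SE 0.49). RPL27A averaged 1101 ± 272 and 2412 ± 1061 CPM, and RPS27 104 ± 28.6 and 391 ± 321 CPM. Of 55 nuclear genes of the respiratory chain and ATP synthase, 46 had a lower estimate (median log2 fold change -0.45). Among them COX7A2, a subunit of cytochrome c oxidase, averaged 509 ± 242 CPM against 1042 ± 199.7, and UQCRQ and UQCR10, subunits of complex III, averaged 473 ± 20.7 against 919 ± 215 and 339 ± 93.4 against 725 ± 233. Without naive replicate 2 the camera adjusted p was 0.0495 for ribosomal proteins and 0.182 for oxidative phosphorylation, and without control replicate 3 it was 0.000610 and 0.0919, so that either library ended the call of oxidative phosphorylation. Without the 4 libraries of fewest detected genes per barcode it was 0.00394 for both fallen lists, and with barcodes that hold the gene counted in place of reads it was 0.336 and 0.145. The RNA quality and nuclear RNA list went the other way without passing, with 4 of 5 genes higher (median log2 fold change 1.17, camera p 0.0412, adjusted p 0.105, and adjusted p = 0.712 with an estimated correlation), and it was among the 4 lists that passed without the 4 libraries of fewest detected genes. The nuclear RNA MALAT1, chosen after its values were seen, took 1.31% ± 0.638 of the counts with naive exosomes and 0.615% ± 0.233 without (SD, n = 3 each; exact permutation p = 0.2).

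The S phase, G2/M and apoptosis lists rose with naive exosomes. For G2/M, 39 of 52 genes had a higher estimate (median log2 fold change 0.63, camera adjusted p 0.00238), and for S phase 32 of 41 (0.61, camera adjusted p 0.0270), while the adjusted p = 0.915 with an estimated correlation for both. MKI67, the gene of the proliferation marker Ki-67, averaged 437 ± 174 CPM with naive exosomes and 124 ± 119 CPM without (SD, n = 3 each; log2 fold change 1.82, SE 0.87), and NEK2, a mitotic kinase, averaged 35.8 ± 8.12 and 5.51 ± 3.30 CPM. RRM2, a subunit of ribonucleotide reductase, averaged 151 ± 23.1 and 44.4 ± 29.2 CPM, and MCM6, a subunit of the replicative helicase, 93.1 ± 42.4 and 23.0 ± 16.8 CPM. Of 23 apoptosis genes, 17 had a higher estimate (median log2 fold change 0.68, camera adjusted p 0.0331, and adjusted p = 0.712 with an estimated correlation). PMAIP1 and BCL2L11, which encode pro-apoptotic proteins, had log2 fold changes of 3.11 (SE 1.15) and 4.17 (SE 1.62), and BIRC3, which encodes an inhibitor of apoptosis, had 2.35 (SE 1.30). PMAIP1 averaged 728 ± 1007 and 84.0 ± 59.2 CPM and rested on naive replicate 2, without which PMAIP1 was at 0.80 and BIRC3 at 1.15. In the 5 lists that passed with naive exosomes 0 members passed edgeR over all genes tested and 0 when adjusted over the list alone, with 6 members at an unadjusted p under 0.05. The G2/M and S phase calls ended without control replicate 1 (adjusted p 0.0514 and 0.0920), control replicate 2 (0.648 for both) or naive replicate 2 (0.214 and 0.438), S phase also without naive replicate 3 (0.0640), and without the 4 libraries of fewest detected genes both turned direction (0.598 and 0.716). The apoptosis call held without naive replicate 3 (0.0194) and was lost without control replicate 1 (0.0920), 2 (0.173) or 3 (0.0780) and without naive replicate 1 (0.162) or 2 (0.182), and it was 0.402 without the 4 libraries of fewest detected genes. With limma and a pseudocount of 1 none of these 3 lists passed (S phase 0.121, G2/M and apoptosis 0.108).

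No single gene passed between naive exosomes and none. edgeR's quasi-likelihood test called 0 of 15979 genes (lowest adjusted p 1.00), limma called 0 and DESeq2 23. An unadjusted p under 0.05 was found for 279 genes, where evenly spread p-values give 799 and other splits of these libraries gave 267 to 681. Of the genes with the smallest p, MT-RNR2, the mitochondrial 16S ribosomal RNA (chromosome M, 1671 to 3229 on GRCh38), took 4.29% ± 0.525 of the counts with naive exosomes and 2.49% ± 0.284 without (SD, n = 3 each; log2 fold change 0.86, SE 0.19). Its reads can be shared with near-identical nuclear copies, so its level is uncertain. VAMP5 had 0 counts in the controls and 6.91 ± 4.54 CPM with naive exosomes, at least 64.5-fold higher against a floor of 3 counts over the group, and RP11-283I3.6 was at least 223-fold higher by the same floor. BACH1-IT1 averaged 32.2 ± 35.7 CPM against 0.0541 ± 0.0936, KLHL15 49.3 ± 53.5 against 0.176 ± 0.306 and PITPNM3 40.8 ± 56.1 against 0.310 ± 0.293. Without naive replicate 1 the log2 fold changes of BACH1-IT1, KLHL15 and PITPNM3 fell from 9.09, 7.84 and 7.02 to 7.67, 6.43 and 4.79. In the lower direction ASIC1, an acid-sensing ion channel, averaged 0.0160 ± 0.0277 CPM against 4.77 ± 0.625, ARTN, a neurotrophic factor, 0.0615 ± 0.106 against 6.80 ± 2.33, and FAM78A 0.121 ± 0.0687 against 4.05 ± 4.38. RP11-705C15.3, FPR1 and CXorf57 had 0 counts with naive exosomes. RP11-705C15.3 averaged 3.14 ± 2.10 CPM in the controls and was at least 35.6-fold lower, while FPR1 and CXorf57 were uneven between control replicates 1, 2 and 3, at 0.149, 88.5 and 2.05 CPM and 7.31, 0.162 and 11.6 CPM. The 2 groups did not overlap in 8.65% of genes, where chance gives 10%.

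With primed exosomes, the single gene nearest to the threshold against no exosomes was MT-RNR2, which did not pass. MT-RNR2 took 4.80%, 5.91% and 4.63% of the counts in the 3 primed libraries and 2.70%, 2.61% and 2.17% in the 3 controls, a mean of 5.11% ± 0.696 against 2.49% ± 0.284 (SD, n = 3 each). Its log2 fold change was 1.44 (SE 0.20, edgeR adjusted p 0.0525). Over its alternatives the log2 fold change ran from 0.79 to 1.77, and the adjusted p from 0.00904, without primed replicate 3, to 1. The estimate depends on the scaling, since the TMM factor of primed replicate 1 was 0.607 while the other factors lay between 0.988 and 1.19, and with the deposited total count as library size it was 0.85. The 12S ribosomal RNA MT-RNR1 took 0.255% ± 0.210 of the counts with primed exosomes and 0.256% ± 0.134 without, and the 13 mitochondrial mRNAs took 2.20% ± 1.78 and 2.08% ± 0.677. The share was 4.70% ± 0.712 over the 6 exosome libraries, and all 6 lay above all 3 controls.

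**Figure D2:**
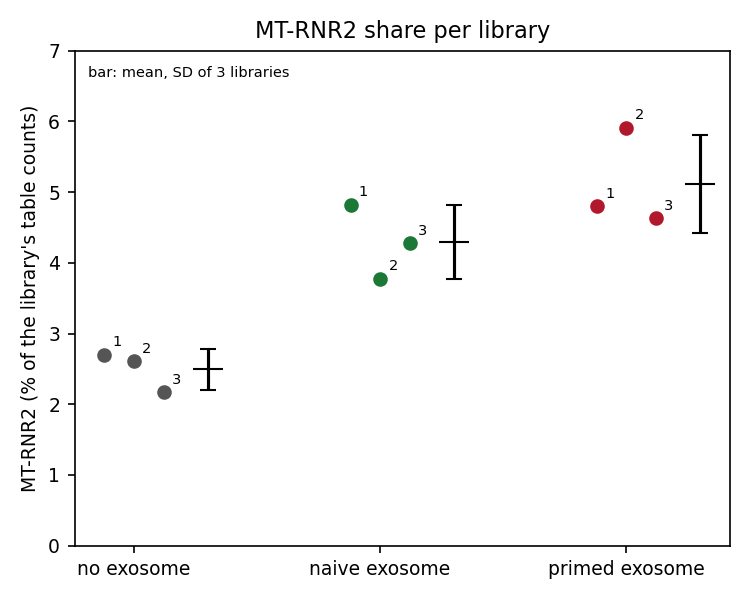
Share of each library's counts that falls on MT-RNR2, in percent, for the 3 groups, with points for the libraries numbered by replicate and a bar for the mean and SD of 3 libraries. The control libraries lie between 2.17% and 2.70%, the naive libraries between 3.77% and 4.82% and the primed libraries between 4.63% and 5.91%.

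Neither a list nor a single gene passed between primed exosomes and none. Of 28 lists, 0 passed camera, 5 had an unadjusted p under 0.05 and 0 passed with an estimated correlation or with fry. The lowest adjusted p was 0.0792, shared by the mitochondrially encoded genes (13 of 15 with a higher estimate, median log2 fold change 0.74), the nuclear oxidative phosphorylation genes (40 of 55, 0.34) and the cholesterol synthesis genes (18 of 27, 0.38). These member counts and medians also depend on the scaling, with a TMM factor of 0.607 in primed replicate 1. Leaving out a single library gave 4 lists without control replicate 3 or primed replicate 3, 3 without primed replicate 1, 2 without control replicate 2 or primed replicate 2 and 0 without control replicate 1. edgeR called 0 of 15979 genes, limma called 0 and DESeq2 313. An unadjusted p under 0.05 was found for 1284 genes, where evenly spread p-values give 799 and other splits of these libraries gave 916 to 2130. Among the genes with the smallest p, SMG9, which takes part in nonsense-mediated decay, averaged 266 ± 342 CPM with primed exosomes and 0.668 ± 0.609 without, PPAPDC1B 112 ± 103 and 1.53 ± 0.627, and NARS2, the mitochondrial asparaginyl-tRNA synthetase, 499 ± 784 and 6.55 ± 3.88 CPM (SD, n = 3 each). THAP9 and ZSCAN32 averaged 229.7 ± 379 and 142 ± 198 CPM against 0.0497 ± 0.0861 for each. Without primed replicate 1 the log2 fold change fell from 6.25 to 2.71 for NARS2, 8.66 to 6.62 for SMG9 and 6.18 to 5.02 for PPAPDC1B. In the lower direction MED8, a Mediator subunit, averaged 0.959 ± 0.398 CPM against 121 ± 123, FBXL15 0.138 ± 0.238 against 50.1 ± 17.5 and CATSPER1 0.0292 ± 0.0505 against 61.6 ± 75.1. Without control replicate 2 the log2 fold change moved from -6.93 to -5.72 for MED8 and from -9.85 to -8.22 for CATSPER1. AL590710.1 and RNU5F-1 had 0 counts with primed exosomes and 14.1 ± 2.38 and 18.3 ± 14.6 CPM without, and were at least 74.6-fold and 96.5-fold lower. The edgeR adjusted p of these genes was 0.586 in each case. The groups did not overlap in 10.0% of genes, where chance gives 10%.

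Between primed and naive exosomes, the nuclear genes of oxidative phosphorylation were higher and the S phase genes lower with primed exosomes. Of 55 oxidative phosphorylation genes, 49 had a higher estimate with primed exosomes (median log2 fold change 0.57, camera adjusted p 1.58e-06, and adjusted p = 0.811 with an estimated correlation). UQCR10 averaged 1834 ± 1938 CPM with primed and 339 ± 93.4 with naive exosomes (SD, n = 3 each; log2 fold change 2.44, SE 0.70), NDUFA2, a subunit of complex I, 509 ± 271 and 106 ± 43.3, UQCRQ 1565 ± 1589 and 473 ± 20.7, and ATP5I, a subunit of ATP synthase, 1186 ± 1874 and 123 ± 81.7. UQCR10, UQCRQ and ATP5I rested on primed replicate 1, without which their log2 fold changes fell from 2.44, 1.73 and 3.27 to 1.03, 0.41 and -0.27, and that of NDUFA2 was 2.26 with it and 1.72 without. Of 41 S phase genes, 29 had a lower estimate with primed exosomes (median log2 fold change -1.26, camera adjusted p 0.00134, and adjusted p = 0.811 with an estimated correlation). CDCA7 averaged 0.292 ± 0.505 CPM with primed and 25.1 ± 22.2 with naive exosomes, and E2F8, a transcription factor of the cell cycle, 0.197 ± 0.269 and 10.3 ± 2.58. The ribosomal protein list rose slightly, with 48 of 78 genes higher (median log2 fold change 0.16, camera adjusted p 0.0317, and adjusted p = 0.811 with an estimated correlation), and its members went both ways, from RPS27 at 2.07 (SE 0.86), and 0.71 without primed replicate 1, to RPS9 at -1.54 (SE 0.80). Member counts and log2 fold changes of this comparison depend on the scaling, since the TMM factor of primed replicate 1 was 0.607. In these 3 lists 0 members passed edgeR over all genes or adjusted over the list alone, with 16 members at an unadjusted p under 0.05. The oxidative phosphorylation call ended without primed replicate 1 (adjusted p 0.0629), the S phase call without naive replicate 2 (0.0724) or primed replicate 2 (0.174), and the ribosomal protein call without naive replicate 1 (0.0579), naive replicate 2 (0.417), primed replicate 1 (0.627) or primed replicate 3 (0.194). Without the 4 libraries of fewest detected genes, which leaves primed replicate 3 alone in its group, none of the 3 passed (0.846, 0.809 and 0.592) and S phase turned direction.

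**Figure D3:**
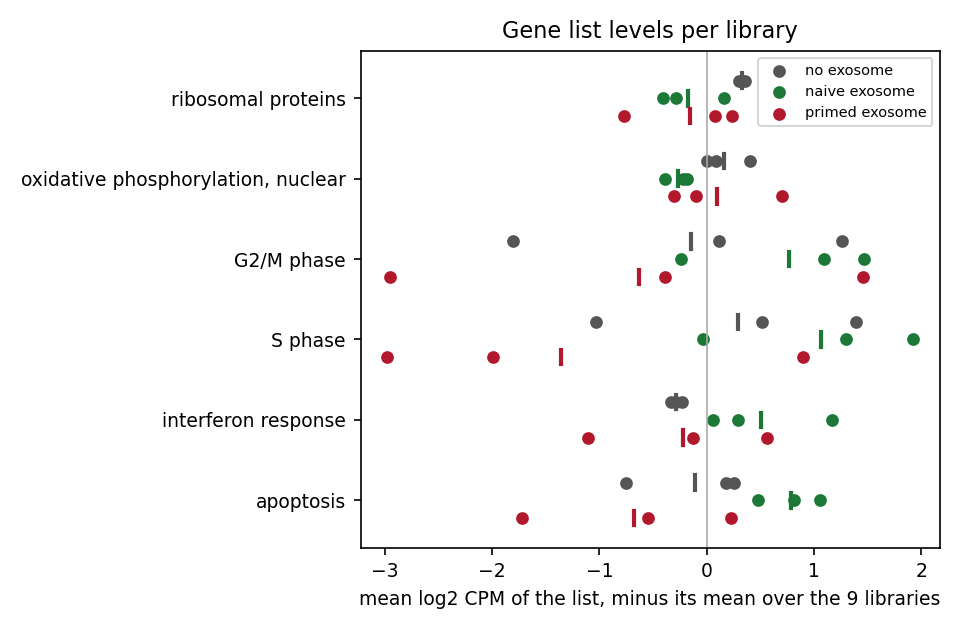
Mean log2 CPM of 6 gene lists in each library, minus the list's mean over the 9 libraries, with points for libraries and short lines for the means of the 3 groups. The ribosomal protein list lies at 0.30 to 0.35 in the controls and at -0.40 to 0.16 in the naive libraries. The oxidative phosphorylation list lies at 0.70 in primed replicate 1 and at -0.30 and -0.10 in the other primed libraries. Values use TMM scaling, whose factor of 0.607 in primed replicate 1 raises all levels of that library over those from plain sums.

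Single genes did not pass between primed and naive exosomes either. edgeR called 0 of 15979 genes (lowest adjusted p 0.584), limma called 0 and DESeq2 395. An unadjusted p under 0.05 was found for 1259 genes, where evenly spread p-values give 799 and other splits of these libraries gave 680 to 2470. NARS2 averaged 499 ± 784 CPM with primed and 9.44 ± 10.2 with naive exosomes, NPM3, a nucleoplasmin family gene, 577 ± 877 and 36.3 ± 1.71, and RP11-748H22.2 6.35 ± 3.87 and 0.0320 ± 0.0554 (SD, n = 3 each). MOB3C averaged 81.5 ± 82.5 CPM against 0.0320 ± 0.0554 and AC005789.11 140.1 ± 237 against 0.412 ± 0.282, with 1 primed library at 0 in each. Without primed replicate 1 the log2 fold change fell from 3.99 to 0.92 for NPM3, 5.71 to 2.19 for NARS2 and 8.41 to 3.11 for AC005789.11. In the lower direction CNOT2, a subunit of the CCR4-NOT deadenylase complex, averaged 1.47 ± 0.215 CPM against 83.4 ± 14.2, and KATNA1, which encodes a microtubule-severing protein, 0.0292 ± 0.0505 against 19.0 ± 6.05. AC007347.1 and AL590710.1 had 0 counts with primed exosomes and were at least 54.0-fold and 49.9-fold lower. The groups did not overlap in 11.6% of genes, where chance gives 10%.

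With both exosome groups pooled against no exosomes, the interferon response and G2/M lists rose and the ribosomal protein list fell. Of 32 interferon response genes, 19 had a higher estimate (median log2 fold change 0.16, mean 0.93, camera adjusted p 0.0428, and adjusted p = 0.760 with an estimated correlation), and 6 had an unadjusted p under 0.05. IFIT3, an interferon-induced gene, averaged 714 ± 624 CPM in the 6 exosome libraries and 58.8 ± 36.6 CPM in the 3 controls (SD; log2 fold change 3.60, SE 1.04, edgeR adjusted p 1.00). Every exosome library lay above every control, naive replicate 3 only just, and a single barcode held 47.0% of the IFIT3 counts of naive replicate 2. The share of barcodes with IFIT3 detected overlapped, at 34.5% to 93.1% in the exosome libraries and 10.1% to 72.8% in the controls. IFIT2 averaged 476 ± 578 and 60.8 ± 64.5 CPM, OASL 222 ± 307 and 13.1 ± 11.3, and OAS1 10.5 ± 9.95 and 0.162 ± 0.281. The log2 fold change of OASL fell from 4.04 to 1.501 without primed replicate 2. Of 52 G2/M genes, 37 had a higher estimate (median log2 fold change 0.56, camera adjusted p 0.0262, and adjusted p = 0.760 with an estimated correlation), with NEK2 at 71.6 ± 75.6 CPM against 5.51 ± 3.30. Of 78 ribosomal protein genes 71 had a lower estimate (-0.41, camera adjusted p 0.0262, and adjusted p = 0.760 with an estimated correlation), with RPLP1 at 1408 ± 398 CPM against 2278 ± 329 and RPLP2 at 1219 ± 411 against 2059.8 ± 391. In these 3 lists 0 members passed edgeR over all genes or adjusted over the list alone. edgeR called 0 of 15979 genes (lowest adjusted p 0.188, for MT-RNR2), with 710 at an unadjusted p under 0.05 where evenly spread p-values give 799, limma called 0 and DESeq2 39. The groups did not overlap in 1.40% of genes, where chance gives 2.38%. The calls depend on single libraries. Of 9 fits that left out 1 library, interferon response passed in 5 and G2/M and ribosomal proteins in 3 each. Counted over all lists, which includes others than these 3, 0 passed without control replicate 1 or naive replicate 2 and 1 without control replicate 2. The count was 2 without naive replicate 3, primed replicate 2 or primed replicate 3, 3 without control replicate 3, and 4 without naive replicate 1 or primed replicate 1. With the replicate number as a block, which naive and primed libraries share through their exosome source, none of the 3 lists passed (interferon response 0.0841, G2/M and ribosomal proteins 0.0724). With median-ratio scaling ribosomal proteins did not pass (0.119). Ribosomal proteins turned direction when barcodes with the gene were counted in place of reads (adjusted p 0.00946), and without the 4 libraries of fewest detected genes none of the 3 lists passed (0.180 to 0.406).

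Genes chosen for their link to stemness, Wnt signalling and the cell cycle did not pass in any comparison. Against no exosomes, CTNNB1, the gene of beta-catenin, had log2 fold changes of -1.04 (SE 0.90) with naive and -1.78 (SE 0.92) with primed exosomes, MYC -0.58 (SE 0.96) and -1.20 (SE 0.97), and CCND1, the gene of cyclin D1, 0.28 (SE 0.53) and 0.58 (SE 0.53). The CDK inhibitor genes CDKN1A and CDKN1B had 0.84 (SE 1.29) and 1.57 (SE 1.57) with naive and -0.20 (SE 1.28) and 3.35 (SE 1.68) with primed exosomes. CD44, a surface marker of stem-like breast cancer cells, had 1.16 (SE 0.98) and 1.22 (SE 0.98), VIM, the gene of vimentin, 0.81 (SE 0.72) and 1.38 (SE 0.73), and MKI67 with primed exosomes 1.07 (SE 0.85). A single barcode held 97.7% of the CD44 counts of primed replicate 2. Between primed and naive exosomes the log2 fold changes were -0.74 (SE 0.90) for CTNNB1, -0.61 (SE 0.96) for MYC, 0.30 (SE 0.53) for CCND1, -1.05 (SE 1.29) for CDKN1A, 1.78 (SE 1.58) for CDKN1B, -0.74 (SE 0.85) for MKI67, 0.06 (SE 0.97) for CD44 and 0.57 (SE 0.71) for VIM. With edgeR the lowest adjusted p of these genes was 0.645 against no exosomes and 0.857 between the exosome groups, both for CDKN1B. Some directions rested on 1 library. Against no exosomes, MYC was at 0.17 with naive exosomes without control replicate 2, CDKN1A at -0.57 with naive exosomes without naive replicate 2 and at 0.35 and 0.19 with primed exosomes without control replicate 1 and primed replicate 1, and CD44 at -0.37 with primed exosomes without primed replicate 1. Between the exosome groups, MYC and CDKN1A were at 0.39 and 0.34 without naive replicate 2, CD44 at -0.23, -0.11 and -1.49 without naive replicate 2, naive replicate 3 and primed replicate 1, and VIM at -0.30 without primed replicate 1. Other directions rested on the fit. With limma and a pseudocount of 1, CCND1 was at -0.15 with primed exosomes against none and at -0.43 between the exosome groups, and with the replicate number as a block CD44 and VIM were at -0.71 and -0.01 between the exosome groups. POU5F1, SOX2 and NANOG are not listed in the table, and their levels were not analysed here.

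Of the 28 lists tested, 22 passed in none of the 4 comparisons. Their lowest camera adjusted p over the comparisons was 0.05004 for the unfolded protein response (naive against none, just above the threshold), 0.0534 for the mitochondrially encoded and cholesterol synthesis lists, 0.0642 for NF-kB and cytokines and for ferritin, redox and metallothionein genes, 0.0835 for DNA repair, 0.105 for RNA quality and nuclear RNA, 0.176 for heat shock, 0.184 for the proteasome, 0.228 for Wnt and beta-catenin, 0.279 for immediate early genes and 0.305 for glycolysis and hypoxia. It was 0.380 for epithelial genes, 0.520 for mesenchymal and matrix genes, 0.555 for p53 targets, 0.562 for CDK inhibitors and quiescence, 0.689 for Notch, histones and vesicle biogenesis, 0.693 for TGF-beta and BMP, and 0.706 for pluripotency and cancer stem cell genes. Markers of MSCs, the cells that gave the exosomes, had a lowest adjusted p of 0.679 over 8 measured genes. Of 17 blood cell markers 2 were listed, too few to test.

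The number of genes detected per barcode varied more between the libraries of a group than between group means. The library medians averaged 3675 ± 1965 genes in the controls, 3276 ± 2091 with naive and 2367 ± 2316 with primed exosomes (SD, n = 3 each). The exact permutation p was 0.7 for naive and 0.6 for primed exosomes against none and 0.7 between them, where 3 libraries against 3 cannot give less than 0.1. The difference between naive exosomes and none was -399, and it turned positive without control replicate 1 (174), control replicate 3 (163) or naive replicate 2 (755.5). The share of barcodes with a high G2/M score, a range cut from a score and not a cell type, was 15.5% ± 18.8 in the controls, 27.2% ± 23.4 with naive and 20.3% ± 28.8 with primed exosomes (exact permutation p 0.8 for both exosome groups against none and 1 between them). After each barcode was thinned to 2000 counts, which left out 82, 56 and 304 barcodes of the 3 groups, the shares were 12.3% ± 11.2, 24.6% ± 15.5 and 14.9% ± 18.6. The difference of 4.83 percentage points between primed exosomes and none turned without control replicate 2 (-2.42) or primed replicate 3 (-11.8), and that of -6.91 between primed and naive exosomes turned without naive replicate 3 (1.76), primed replicate 1 (2.02) or primed replicate 2 (0.803). Of all barcodes, 98 lay within 0.1 SD of the limit of the score.

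Clusters of barcodes followed libraries and not treatments. Leiden clustering gave 21 clusters, and in all 21 more than 80% of the barcodes came from 1 library. In exact permutation tests of cluster shares 0 clusters passed (lowest adjusted p 0.875 for either exosome against none with n = 6 and 3, and 1 in the other comparisons with n = 3 each, where no p under 0.1 is possible), and no cell type was named. For either exosome against none, clusters that lie mostly in 1 library also leave a small p out of reach (lowest unadjusted exact permutation p 0.310). These tests therefore say nothing about the treatments.

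The naive and primed log2 fold changes against the same controls correlated across 15979 genes with r = 0.346. Genes are not independent replicates, and 20 simulations of unchanged groups against the same controls gave a median r of 0.493 (0.475 to 0.507). Without control replicate 1, 2 or 3 the correlation was 0.5003, 0.429 and 0.503, but the simulations kept all controls, so their range is no chance value for these fits. The covariance was 1.01 against 1.33 in the simulations (1.27 to 1.40). Both observed values lie below all 20 simulated ones, so the simulations do not reproduce these data, and whether the 2 exosome kinds share an effect beyond the shared controls stays open.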

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

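The tests in this part were chosen only after the result was seen. The submitters' own mitochondrial percent per barcode, a value deposited beside the gene counts and computed from the same mitochondrial genes, was higher in the naive exosome libraries than in the controls. The library medians averaged 4.24% ± 0.729 with naive exosomes and 2.5998% ± 0.693 without (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), and 3.57% ± 1.21 with primed exosomes.

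Among the mitochondrial RNAs, MT-RNR2 took a higher share of all counts of its library in all 6 exosome libraries than in all 3 controls (4.70% ± 0.712 against 2.49% ± 0.284). The tables argue against a few barcodes with large totals as the whole cause, since the median over barcodes was 3.82% in the lowest exosome library and 2.91% in the highest control, and against few detected genes per barcode, since the difference between exosome and control libraries was 2.21 percentage points and, after the trend on detected genes within them, 2.17 (95% confidence interval 0.980 to 3.35). More mitochondrial RNA of every kind stays open. MT-RNR1 took 0.256% ± 0.159 of the counts in the exosome libraries and 0.256% ± 0.134 in the controls. The mitochondrial mRNAs took 2.16% ± 1.15 and 2.08% ± 0.677. These means were alike, unlike those of MT-RNR2, but their spread is too wide to decide. The mitochondrial mRNA share lay above all controls in 1 of the 6 exosome libraries, but MT-RNR2 did not rise over the mRNAs past the threshold (log2 difference 0.96, exact permutation p = 0.155). For either exosome against none 13 of 15 mitochondrially encoded genes, MT-RNR2 among them, had a higher estimate (median log2 fold change 0.50, camera adjusted p 0.0534, and adjusted p = 0.760 with an estimated correlation). The mean log2 CPM of that list, minus its mean over the 9 libraries, was 1.72 in primed replicate 1. It was -1.11 to 0.27 in the other exosome libraries and -0.78 to 0.19 in the controls, so the rise was largest in 1 library. The level of primed replicate 1 also depends on the scaling, since its TMM factor was 0.607. Reads shared with the 13 nuclear copies of the mitochondrial ribosomal RNA also stay open, since the copies took 1.64 times the control share (exact permutation p = 0.167), and a difference between library batches was not tested because the labels give none. An effect of the exosomes, or ribosomal RNA carried by them, may also explain it and was not tested, so MT-RNR2 is a hypothesis, found and weighed in the same 9 libraries (edgeR adjusted p 0.188 for either exosome against none). An exact permutation test of its share gave p = 0.0119 with 6 libraries against 3, the smallest possible, and 0.0833 adjusted over 7 measures, and neither value counts that the gene was picked from 15979 after its values were seen. This test, the other exact tests of 6 libraries against 3 and the confidence interval also treat the exosome libraries as independent. Naive and primed libraries of the same number share an exosome source, which none of them takes into account.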

How the results depend on the processing

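The alternatives added after the data were seen are the robust dispersion, limma with a pseudocount of 5, the deposited total count as library size, the barcodes left out by share or shared bases, barcodes with the gene in place of counts, the 4 libraries of fewest detected genes left out, and thinning, and the tests that use them were chosen only after the result was seen. Where no cause is given, the cause was not tested.

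The count of 0 genes held in 25 of 27 alternatives that left out 1 library and in 64 of 71 others (0 to 1 for either exosome against none and for primed exosomes against none, with the 1 gene without primed replicate 3 in both). DESeq2 called 39 genes for either exosome, 23 for naive and 313 for primed exosomes against none, and 395 between primed and naive exosomes, and splits of the libraries by detected genes are given under other observations. For primed exosomes against none 1 gene, MT-RNR2, passed with the replicate number as a block, with no filter on low counts and with the 20% of barcodes of fewest detected genes left out (adjusted p 0.0217, 0.0349 and 0.0346; range over its alternatives 0.00904 to 1). Scaling moved the median log2 fold change of all genes, which was -0.067 for primed exosomes against none, to 0.16 with median-ratio scaling and -0.57 with the deposited total count, and for primed against naive exosomes from -0.083 to 0.13 and -0.54.

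The number of lists that passed depended on most choices, and apart from the estimated correlation the cause was not tested. In the lists that passed for naive exosomes against none that correlation lay far above the preset 0.01. It was 0.414 for G2/M, 0.339 for S phase, 0.257 for ribosomal proteins, 0.146 for oxidative phosphorylation and 0.0558 for apoptosis. For either exosome against none it was 3, and 0 with the replicate block, the estimated correlation or fry, 1 with limma and a pseudocount of 1 or 5, without barcodes sharing 11 bases or without the 4 libraries of fewest detected genes, 5 with barcodes with the gene, and 0 to 4 with a library left out. For naive exosomes against none it was 5, and 0 with the estimated correlation or fry, 2 with limma and a pseudocount of 1, without barcodes sharing 11 bases or with barcodes with the gene, 3 with a pseudocount of 5, and 1 to 6 with a library left out. For primed exosomes against none it was 0, and 2 with median-ratio scaling, 1 without barcodes over 2% of their library, without barcodes sharing 11 bases, with the deposited total count or without the 4 libraries of fewest detected genes, 6 with barcodes with the gene, and 0 to 4 with a library left out. Between primed and naive exosomes it was 3, and 0 with the estimated correlation or fry, 5 without barcodes over 2% of their library, 6 with barcodes with the gene, and 1 to 4 with a library left out. The ribosomal protein call of naive exosomes held in 15 of 18 alternatives and in all 6 that left out a library, the oxidative phosphorylation call in 13 of 18 for naive exosomes and 14 of 18 between primed and naive exosomes, and the apoptosis call in 5 of 18. S phase held in 13 of 18 between primed and naive exosomes and 7 of 18 for naive exosomes, G2/M in 8 of 18 for naive exosomes and ribosomal proteins in 9 of 18 between primed and naive exosomes, and for either exosome G2/M held in 6, interferon response in 8 and ribosomal proteins in 9 of 21. With median-ratio scaling the count for either exosome stayed at 3 although ribosomal proteins no longer passed (0.119; range over their alternatives 1.78e-06 to 0.760). Lists turned direction for ribosomal proteins of either exosome with barcodes with the gene (0.00946) and, without the 4 libraries of fewest detected genes, for S phase and G2/M of naive exosomes (0.716 and 0.598) and S phase between primed and naive exosomes (0.809). Where 1 library was left in a group it was assumed to vary like the other groups.

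The replicate number as a block changed the lists of either exosome against none from 3 to 0 and the genes of primed exosomes against none from 0 to 1, and left the lists of naive exosomes at 5 and those between primed and naive exosomes at 3. Deviations from the group means correlated between control and naive libraries of the same number at 0.0580, -0.0464 and 0.134 and between control and primed libraries at 0.0515, 0.0410 and 0.141. For 7 of the 9 libraries the highest such correlation with a library of another group was with the same number.

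Of 102 named log2 fold changes, 21 turned direction in at least 1 alternative, and the cause was not tested. In at least 1 alternative 25 passed the threshold, MT-RNR2 as given above and the others with DESeq2. Without the 4 libraries of fewest detected genes the values were MOB3C -2.81, CTNNB1 0.021, MYC 0.22, CDKN1A 0.44, MKI67 0.039, CD44 -0.83, ATP5I -0.25 (primed against naive) and CDKN1A -1.12 (naive) and CKAP2 -0.48 (either). With the mean of log values over barcodes the values were CCND1 -0.098, CDKN1A -0.082, CDKN1B -0.0042 (naive) and CCND1 -0.49, CD44 -0.013 (primed) and CCND1 -0.39, CD44 -0.58, VIM -0.29 (primed against naive) and CKAP2 -0.062 (either). With limma and a pseudocount of 1 the values were CDKN1A -0.052 (naive) and CCND1 -0.15 (primed) and CCND1 -0.43, CD44 -1.01, VIM -0.14 (primed against naive). With limma and a pseudocount of 20 the values were CDKN1A -0.022 (naive) and CCND1 -0.13 (primed) and CCND1 -0.41, CD44 -0.91, VIM -0.12 (primed against naive). With limma and a pseudocount of 5 the values were CDKN1A -0.042 (naive) and CCND1 -0.15 (primed) and CCND1 -0.43, CD44 -0.99, VIM -0.13 (primed against naive). Without barcodes over 2% of their library the values were CDKN1A -0.038 (naive) and MYC 0.44 (primed against naive). Without barcodes sharing 11 bases the values were CDKN1A -0.43 (naive) and MYC 0.34 (primed against naive). With barcodes with the gene in place of counts the values were CDKN1B -0.0018 (naive) and CDKN1A 0.34 (primed) and MYC 0.22, CDKN1A 0.036, MKI67 0.20 (primed against naive) and RPL27A 0.41, RPS21 0.37, RPLP1 0.40, RPLP2 0.36 (either). With median-ratio scaling the values were CDKN1A 0.021 (primed). With the deposited total count as library size the values were CCND1 -0.16, CD44 -0.59, VIM -0.080 (primed against naive). With the replicate number as a block the values were CD44 -0.71, VIM -0.014 (primed against naive). With a mean CPM of at least 50 the values were CD44 -0.13 (primed against naive). With a library left out they ran from -1.59 to 0.17 for MYC (naive), -0.57 to 1.42 for CDKN1A (naive), -0.84 to 0.35 for CDKN1A (primed), -0.37 to 1.87 for CD44 (primed), -0.99 to 0.39 for MYC (primed against naive), -1.65 to 0.34 for CDKN1A (primed against naive), -1.49 to 0.72 for CD44 (primed against naive), -0.30 to 1.16 for VIM (primed against naive) and -0.27 to 3.94 for ATP5I (primed against naive).

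The correlation of naive and primed effects was 0.346, and 0.396 with a mean CPM of at least 50, 0.398 and 0.428 with limma and pseudocounts of 1 and 20, and 0.429 to 0.503 with a control left out. The difference in detected genes ran with a library left out from -1534 to 756 for naive exosomes against none. The difference in the share of barcodes with a high G2/M score ran from -11.8 to 15.4 percentage points for primed exosomes against none and from -23.5 to 2.02 between primed and naive exosomes. Clusters at resolutions of 0.3 and 1.0 and with another seed also gave 0 that passed, which shows no stability. In 3 of the 4 comparisons 3 libraries against 3 cannot give a p under 0.1. For either exosome against none, clusters that lie mostly in 1 library leave a small p out of reach as well.

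The alternatives for the share of barcodes with POU5F1 were not run because the gene is not listed, and the fit to the compared samples alone is the same as the fit to all 9 libraries for either exosome. In data simulated for naive exosomes against none with the dispersions of these libraries, 0% of genes changed by 2 on the log2 scale and 2% of those changed by 4 were recovered, so that most changes of this size would be missed there. Barcodes under 2000 counts, 442 of 2547, were left out by thinning.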

Other observations

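The tests in this part were chosen, or their outcome first stated, only after the result was seen.

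When the samples were split in other ways into groups of the same sizes, chance was not excluded for the lists of either exosome against none, since 56 of the 84 splits gave at least as many lists as the real 3 (highest other 8). The real split gave 0 genes in edgeR (highest other 2), so that all 84 splits must give at least as many and the count says nothing about chance. In that fit of exosome against none the real split had 428 genes at an unadjusted p under 0.05 and the other splits 306 to 3000, and DESeq2, fitted to the 3 groups, called 39. For the comparisons of 3 against 3 samples the 10 splits are too few for a share under 0.05. There the real values and the highest of the other splits were 5 and 6 lists for naive exosomes against none (4 of 10 splits with as many) and 3 and 7 lists between primed and naive exosomes (7 of 10). They were 0 and 0 genes in each comparison and 0 and 9 lists for primed exosomes against none, where a real count of 0 makes 10 of 10 certain and tells nothing about chance. In edgeR the genes at an unadjusted p under 0.05 were 279 for naive and 1284 for primed exosomes against none, and 1259 between primed and naive exosomes. The other splits gave 267 to 681, 916 to 2130 and 680 to 2470, so each real count lay within their range. DESeq2 called 23, 313 and 395.

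DESeq2 called genes where edgeR called 0, and for primed exosomes against none the number of calls may follow the number of genes detected per barcode. In DESeq2, 8 of the 10 splits gave at least the 23 genes of naive exosomes against none (highest other 139), 2 of 10 at least the 313 of primed exosomes against none (highest other 1110), and 2 of 10 at least the 395 between primed and naive exosomes (highest other 1553). Splitting the same 6 libraries by their median detected genes gave 1110 genes for primed exosomes and none, several times the real count, which points to a structure of these samples other than the treatment. For naive exosomes and none it gave 32, close to the real 23 and reached or passed by other splits. Between primed and naive exosomes this split gave 168 genes, fewer than the real groups, which argues against detected genes as the whole cause there, and another split gave 1553. In each comparison the split with the most DESeq2 genes also parted the libraries by the share of barcodes with a high G2/M score. These shares were 0.629% to 8.75% against 36.5% to 44.5% for naive exosomes and none. They were 0.986% to 4.89% against 8.75% to 53.6% for primed exosomes and none, where detected genes gave the same split. Between primed and naive exosomes they were 0.629% to 4.89% against 36.5% to 53.6%. This was seen after the splits were made, and what sets them apart was not tested.

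Barcodes resembled their library more than their group. Of 2097 genes found in over 50% of the barcodes of each of the 4 libraries with the most detected genes, 393 were found in under 2% of the barcodes of primed replicate 1, 120 in primed replicate 2 and 30 in control replicate 2, where thinning to the counts of those barcodes predicts 0, which argues against low counts per barcode. KRT18, chosen after its values were seen, was detected in 0.154% of the barcodes of primed replicate 1 and in 14.8% to 94.9% in the others. A candidate explanation is that barcodes of a library drew on one pool of RNA, amplified from few molecules. In 8 of 9 libraries the G2/M genes varied together across barcodes no more than the highest of 200 random gene sets, but a planted 3-fold difference in 25% of barcodes was found in 6 of 9 libraries. The G2/M genes also lay at or above the 95.5th percentile of the random sets in 6 of 9 libraries. Chance gives 0.45 libraries above the 95th. These were control replicates 1 and 3, naive replicates 2 and 3, and primed replicates 1 and 3. Apart from primed replicate 1, this goes against a single pool as the whole cause in them. The test cannot decide this for primed replicates 1 and 2 and control replicate 2, which lost the largest numbers of those common genes. The planted difference was missed there, and their percentiles were 95.5, 83.0 and 68.0. In naive replicate 1 the planted difference was found, but the G2/M genes lay only at percentile 64.5, which does not go against a single pool there. That library lost 7 of the common genes, where thinning predicts 0. How far barcodes shared RNA stays open.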
